A study of Homo sapiens with 6 samples.

How the data were processed

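RNA-seq of polyadenylated RNA was performed on MDA-MB-231 cells transfected with an siRNA duplex against SF3B6 or with a non-targeting duplex, with 3 libraries per group. Per the labels' protocols, transfection used a lipid reagent, RNA was treated with DNase, and libraries were strand-specific, made by removing the dUTP-marked cDNA strand. The sample titles all name MDA-MB-231. The cell line field of the labels counts upward from that name across the samples, and the titles were used. Groups and replicate numbers were taken from the titles.

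The read counts per gene were deposited by the authors as whole numbers without normalization, for 39323 genes. HISAT2, DESeq2 and the genome build hg38 are named in the submitters' processing notes, with no versions. The read counter, its use of strand and the annotation release are not given in the sources used here, so antisense and overlapping genes can share reads. The FPKM values were also deposited by the authors, for 39210 genes and rounded to 2 decimals. The ratio of counts to FPKM differed between libraries by a single factor, within 2% for every gene above 5 FPKM in all libraries. The count table held only genes with at least 1 read over the 6 libraries.

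Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, scaled with TMM factors and tested with the quasi-likelihood test (glmQLFit and glmQLFTest), siSF3B6 against siNC, without a replicate block. P-values were adjusted by Benjamini-Hochberg over all 16869 genes tested, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM computed from the counts. Gene lists (32 in number, 898 genes, of which 838 were tested) were written from general knowledge before the data were examined. Lists with at least 5 tested members, 30 of them, were tested with camera at a preset correlation of 0.01. They covered splicing, proliferation, stress, immune, signalling, adhesion and metabolic genes, and markers of other cell types.

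Genes were named by a rule fixed before the data were examined. It took SF3B6 and its SF3b partners, and the 10 largest positive and 10 largest negative log2 fold changes among called genes with a mean of at least 5 CPM, groups that do not overlap and a symbol. It also took up to 4 called members, of at least 5 CPM and the largest change, from each list that passed the set test and from each proliferation or splicing list, and up to 2 from every other list. This gave 107 genes, some of which are not reported here.

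GENCODE release 29 on GRCh38, which is not stated to be the annotation of the authors, gave gene positions, introns, transcript length and GC content (longest transcript of each gene) and 3' UTRs. It covered 99.6% of the 13507 tested protein-coding genes, and 99.0% of them with a 3' UTR. Gene identifiers and symbols are those of the deposited tables. Seed matches were compared by the rank-sum statistic with other 7-base words found in a number of genes within 10% of the seed's own. The GC and length offset was a lowess curve (span 0.3) of each library's deviation from the mean over libraries. Exonic overlap was computed from all annotated exons. Among the named genes with opposite-strand overlap, OIP5 shares 38.0% of its exonic bases with an antisense gene, DDIT4 41.2%, ANKRD37 35.2%, PRPF31 32.0%, IER3 26.5%, SMG6 25.4%, SNHG7 25.2%, RAD54L 25.1%, FANCA 23.6% and FDPS 18.6%. On the same strand, MT-ATP8 shares 22.2%, SNRPB 20.0%, TAF1D 11.2% and POLD1 8.6%.

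The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE factors, library size only, no filter beyond 1 read in all libraries, at least 1 CPM in 3 libraries, a replicate block, robust dispersion, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) for genes of at least 0.5 mean FPKM or without that filter. Leaving out each library, camera with an estimated correlation and fry were further alternatives. The GC and length offset, leaving out mitochondrial genes, siNC replicate 3 as the lone control, leaving out the libraries numbered 3, and the seeds of the passenger strands were added after the data were examined. With siNC replicate 3 as the lone control, that library is assumed to vary like the siSF3B6 libraries.

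The gene test was tested on simulated counts for this comparison, drawn for 16642 genes from the real means, depths and dispersions. It recovered 14% of genes changed 1.25-fold, 86% of those changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold, with 15 false calls. With the observed GC trends added to the simulation, in 16662 genes, it made 105 false calls, and 11 with the offset. The trends added were the lowess curves that the offset fits, which favours the offset. In 16869 simulated genes, a list raised 1.25-fold was called and 0 of 20 unchanged lists were. The genes were drawn independently of each other and the unchanged lists at random. The simulated lists thus cannot show false calls that come from correlation between the genes of a list. In the simulated seed step, run on 13369 genes, a planted shift of -0.1 put 100% of 20 words in the lowest 5% of words. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the sequence analysis and figures.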

Results

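The question stated in the series design was what SF3B6 does in MDA-MB-231 cells, a human triple-negative breast cancer line with mesenchymal features. SF3B6 (also called p14) is a small subunit of SF3b, the part of the U2 snRNP that contacts the branch point of introns. Polyadenylated RNA was sequenced from 3 libraries of cells transfected with a small interfering RNA against SF3B6 (siSF3B6) and from 3 libraries of cells given a non-targeting siRNA (siNC). The design text calls the replicates biological. No label says whether they came from separate cultures or days, so p-values measure the spread between these libraries. Gene totals were 29627499, 28504091 and 33754386 reads in siNC replicates 1 to 3 and 30684131, 38546037 and 31326673 in siSF3B6 replicates 1 to 3.

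The libraries differed within groups as well as between them. Mitochondrially encoded genes took 3.38%, 3.93% and 9.07% of reads in siNC replicates 1, 2 and 3, and 10.8%, 10.6% and 11.8% in the siSF3B6 replicates. At least 1 read was found for 30930, 32041 and 24579 genes in siNC and for 24516, 25566 and 24723 genes in siSF3B6. At least 10 reads were found for 16639 to 17241 genes in every library. The excess lay in genes with 1 to 9 reads, 13952 and 14956 in siNC replicates 1 and 2 against 7731 to 8325 in the others. It sets siNC replicates 1 and 2 apart from all other libraries and is thus partly confounded with group. On both measures siNC replicate 3 lay nearer to the siSF3B6 libraries than to the other siNC libraries. The mean chi-square per gene was 2.94 between siNC replicates 1 and 2 and 2.35 between siSF3B6 replicates 1 and 2. It was 19.3 to 23.1 for every pair that held a replicate 3. No pair agreed within sampling noise, and all 6 libraries were counted separately, which does not show that they are independent. Replicates 1 and 2 of each group were far closer to each other than to replicate 3. If they share a culture, fewer than 3 units per group are independent and the p-values are too small. Fits of the libraries numbered 1 and 2 alone hold only these close pairs. Their p-values measure a narrower spread than those of all 6 libraries, so a pass there is weaker evidence.

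**Figure D1:**
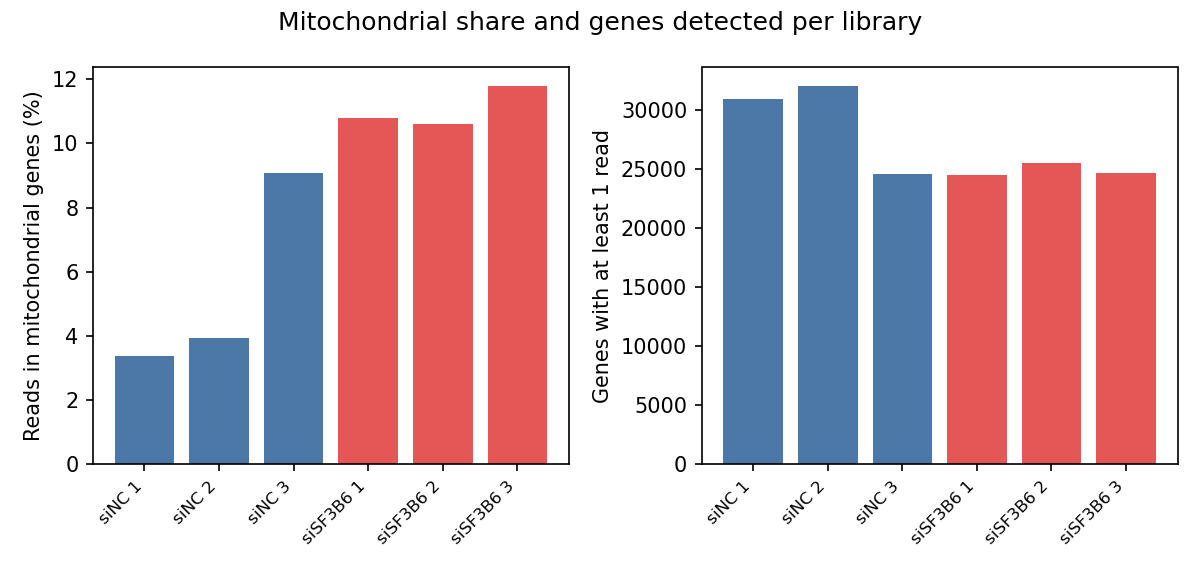
Bars give, for each of the 6 libraries, the percentage of reads in mitochondrially encoded genes (left axis panel) and the number of genes with at least 1 read (right panel), with siNC in blue and siSF3B6 in red. siNC replicate 3, at 9.07% and 24579 genes, lies closer to the siSF3B6 libraries than to siNC replicates 1 and 2.

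SF3B6 itself fell to 25.6% of its siNC level. Its TMM-scaled count was 86.4, 80.6 and 102 CPM in siNC and 22.5, 25.0 and 21.3 CPM in siSF3B6, a log2 fold change of -1.96 (SE 0.104, n = 3 per group; edgeR quasi-likelihood adjusted p = 1.43e-07). The exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 against 3 allows. SF3B6 (ENSG00000115128.7) lies on chromosome 2 at 24067584 to 24076443, minus strand, of GRCh38. The siRNA target GGAGGAACAGTTGAAGCTT matched the reference transcripts at 24067804 to 24067822, inside the coding sequence in exon 4 of 4, and matched no other gene exactly. The non-targeting duplex matched 0 genes. Among the 6 SF3b partners, SF3B1, the largest subunit, rose by a log2 fold change of 0.39 (SE 0.087, adjusted p = 0.00296), or 0.21 (adjusted p = 0.00437) with an offset for GC content and length. Its call was lost with siNC replicate 3 as the lone control (0.32, adjusted p = 0.125) and with unfiltered log2(FPKM + 1) (0.0643). The others did not pass the threshold: SF3B2 had 0.22, SF3B3 0.18, SF3B4 0.29, SF3B5 -0.15 and PHF5A -0.21. SF3B2 passed it with DESeq2 (adjusted p = 0.0228), SF3B4 without siNC replicate 3 (0.00169) or siSF3B6 replicate 3 (0.0442) and with the offset (0.0112), and PHF5A with that offset (0.0122). Within the libraries numbered 1 and 2, close pairs whose p-values measure a narrow spread, SF3B3 passed it (0.00171), as did SF3B2, SF3B4 and PHF5A. With the replicate number as a block, SF3B2 (0.0254), SF3B3 (0.0281) and PHF5A (0.0238) passed it. As a list the partners did not pass the set test (camera adjusted p = 0.529, against 0.0233 with fry, which does not compare a list with other genes), with 1 member past the threshold over all genes, and 4 higher and 1 lower adjusted over the list alone.

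**Figure D2:**
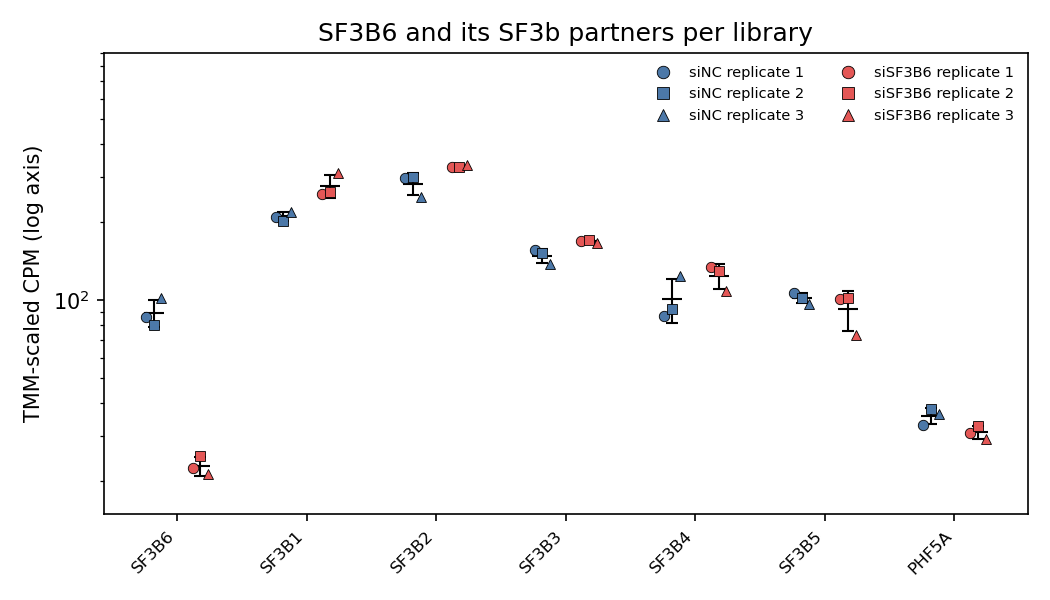
TMM-scaled CPM (log axis) of SF3B6 and its SF3b partners in each library; symbols mark the replicate, blue siNC and red siSF3B6, with bars for the mean ± SD (n = 3). SF3B6 lies between 80.6 and 102 CPM in siNC and between 21.3 and 25.0 CPM in siSF3B6.

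Across the transcriptome, genes for inflammatory mediators and interferon-induced proteins were at the top of those higher in siSF3B6. CXCL8, the neutrophil chemokine interleukin-8, went from 18.8 ± 2.34 to 130 ± 8.76 CPM (SD, n = 3), a log2 fold change of 2.80 (SE 0.102), and IFI44L, an interferon-induced gene, from 2.93 ± 0.782 to 21.6 ± 1.61 CPM, a log2 fold change of 2.88 (SE 0.152). The other 8 of the 10 most raised named genes were LINC02574 (2.16), FILIP1L (2.15), IFI27 (2.07), the chemokine CXCL1 (1.97), the prostaglandin synthase PTGS2 (1.87), the mitochondrial transfer RNA gene MT-TS1 (1.83), the immediate-early gene FOS (1.82) and the kinase FRK (1.80). Next to SF3B6, the 9 most lowered were the cytokine IL11 (-1.89), the proteoglycan CSPG4 (-1.66), OIP5 (-1.61) and CENPM (-1.43), which act at centromeres, the actin regulator VASP (-1.51), the transporter SLC1A7 (-1.44), the cyclin CCNA1 (-1.44), the protease LGMN (-1.40) and VASN (-1.39). VASP went from 168 ± 21.6 to 59.0 ± 5.07 CPM. MT-TS1 is among the genes whose siNC libraries differ most (5.59 ± 5.60 CPM). Its call was lost with DESeq2 (adjusted p = 0.0648) and with robust dispersion in edgeR (0.139). Without siNC replicate 3 its log2 fold change was 3.09.

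Of 16869 genes tested, 6889 changed at an adjusted p under 0.05, 3509 higher and 3380 lower in siSF3B6 (edgeR quasi-likelihood test, Benjamini-Hochberg). Most of these differences were small: 62.9% of the calls were under 1.5-fold, and 680 genes changed at least 2-fold, 381 higher and 299 lower. The groups did not overlap for 52.1% of genes, against 10% by chance. Protein-coding genes made up 3134 of the higher and 3042 of the lower calls, and long noncoding RNAs 274 and 268. With siNC replicate 3 as the lone control, 2471 genes were called, and within the libraries numbered 1 and 2 alone 9470. The 9470 calls rest on the narrow spread of the close pairs. Scaling by library size without TMM factors moved the median of all genes by -0.10 and turned the split to 2459 higher and 4558 lower.

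Genes of DNA replication and the G1/S transition were lower in siSF3B6. Of 57 members, 49 fell and 3 rose (51 and 4 adjusted over the list alone), with a median log2 fold change of -0.61 (camera adjusted p = 3.55e-27, and adjusted p = 0.0125 with an estimated correlation). The transcription factor E2F1 went from 119 ± 11.3 to 46.7 ± 4.12 CPM, a log2 fold change of -1.34 (SE 0.095). E2F2 fell by 1.33 on the log2 scale, CDC45, a part of the replicative helicase, by 1.19, and POLD1, the catalytic subunit of DNA polymerase delta, by 1.13. In DNA damage repair, 18 of 30 genes fell and 0 rose, with the same numbers adjusted over the list alone (median -0.32, adjusted p = 9.11e-08, and adjusted p = 0.155 with an estimated correlation). Among those that fell were RAD54L (-1.15), FANCA (-0.93) and FANCD2 (-0.90), which act in homologous recombination or crosslink repair. In the list of G2/M and mitosis, 27 of 64 genes fell and 5 rose (29 and 6 adjusted over the list alone; median -0.18, adjusted p = 7.72e-05, and adjusted p = 0.385 with an estimated correlation). With the GC and length offset 49 of the G2/M and mitosis genes fell and 3 rose (median -0.27, adjusted p = 5.17e-10), and 2 rose without siNC replicate 2, 3 without siNC replicate 1 or siSF3B6 replicate 3 and 8 without siNC replicate 3. Its called members of at least 5 CPM with the largest changes were MYBL2 (-1.04), ESPL1, the protease separase (-0.86), AURKB (-0.85) and CDCA5 (-0.74). With siNC replicate 3 as the lone control the medians were -0.62, -0.40 and -0.26.

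Interferon-induced genes were higher. Of 38 tested members of the type I interferon list, 27 rose and 4 fell (28 and 5 adjusted over the list alone), with a median log2 fold change of 0.49 (adjusted p = 2.90e-17, and adjusted p = 0.0125 with an estimated correlation). Beside IFI44L and IFI27, IFI6 went from 18.8 ± 2.95 to 65.4 ± 10.5 CPM, a log2 fold change of 1.80, and OAS1, a sensor of double-stranded RNA, from 12.5 ± 0.482 to 40.7 ± 3.99 CPM, a log2 fold change of 1.70. Of 30 NF-kB and inflammatory cytokine genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone; median 0.89, adjusted p = 5.24e-17, and adjusted p = 0.0883 with an estimated correlation). The gene that fell was IL11, from 23.2 ± 2.34 to 6.23 ± 0.897 CPM. Of 24 AP-1 and immediate-early genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone; median 0.40, adjusted p = 9.11e-08, and adjusted p = 0.0883 with an estimated correlation), among them FOS, EGR1 (1.73), IER3 (0.96) and SPRY2 (0.93). With siNC replicate 3 as the lone control the 3 medians were 0.47, 0.92 and 0.40.

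**Figure D3:**
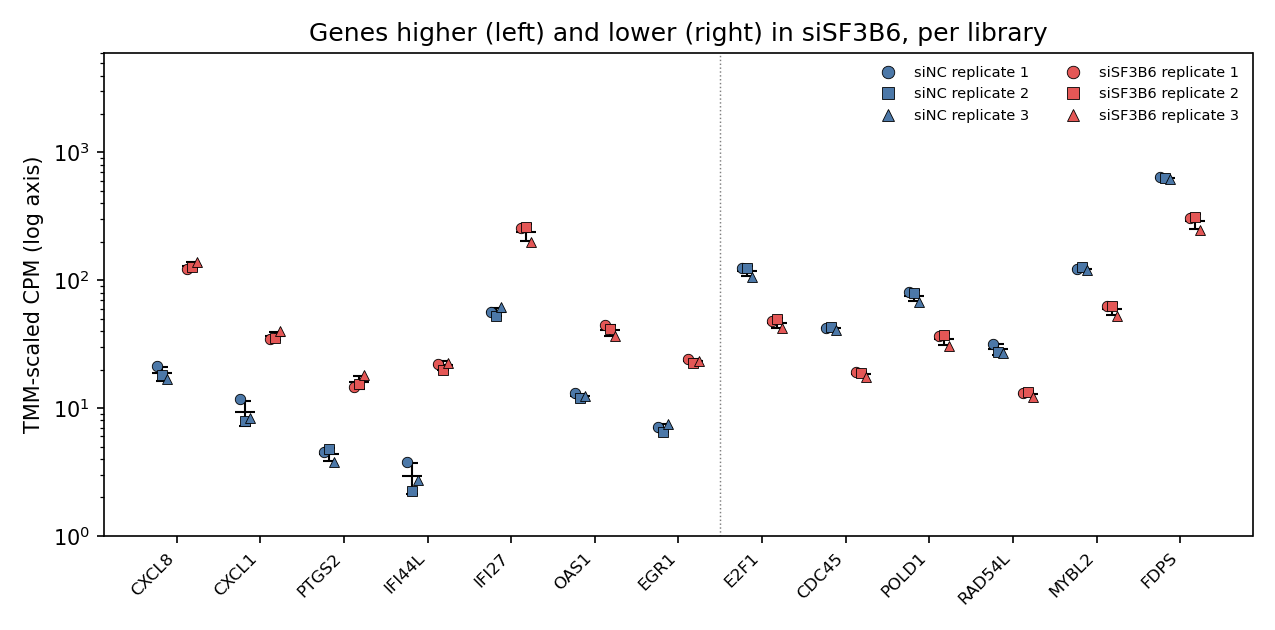
TMM-scaled CPM (log axis) in each library for 7 genes higher and 6 genes lower in siSF3B6, with siNC in blue, siSF3B6 in red, a symbol per replicate and bars for the mean ± SD (n = 3). CXCL8 stands at 18.8 CPM in siNC and 130 CPM in siSF3B6, and E2F1 at 119 and 46.7 CPM.

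Metabolic genes moved in both directions. Of 24 genes of cholesterol synthesis and its regulation, 20 fell and 2 rose, also when adjusted over the list alone (median -0.40, adjusted p = 8.37e-09, and adjusted p = 0.117 with an estimated correlation). FDPS, which makes farnesyl diphosphate, went from 634 ± 8.71 to 290 ± 37.4 CPM, a log2 fold change of -1.13, and MVD (-1.16) and EBP (-0.92) fell as well. Of 33 genes of glycolysis and the hypoxia response, 20 rose and 2 fell, also when adjusted over the list alone (median 0.37, adjusted p = 1.90e-07, and adjusted p = 0.385 with an estimated correlation). ADM (1.30), PDK1 (1.01), ANKRD37 (1.01) and the glucose transporter SLC2A3 (0.89) changed most among its called members of at least 5 CPM. With siNC replicate 3 as the lone control the medians of the 2 lists were -0.34 and 0.45.

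All 15 mitochondrially encoded genes passed the threshold upward, also when adjusted over the list alone (median 1.16, adjusted p = 3.68e-05, and adjusted p = 0.566 with an estimated correlation). The siNC libraries were far apart: MT-CYB had 2681 ± 2036 CPM in siNC and 7034 ± 219 CPM in siSF3B6. The list median was 1.87 among the libraries numbered 1 and 2 and 0.31 with siNC replicate 3 as the lone control, where 7 of the 15 passed; leaving out single libraries moved it between 0.85 and 1.90. Without siSF3B6 replicate 3 the threshold was passed by 6 of the 15, without siNC replicate 2 by 9, and without siNC replicate 1 by 10. The fry test did not pass (adjusted p = 0.0828). With DESeq2 the calls of MT-CYB (1.39, adjusted p = 0.0769), MT-CO2 (1.37, adjusted p = 0.099), MT-ATP8 (1.33, adjusted p = 0.13) and MT-ND3 (1.33, adjusted p = 0.134) were lost. With robust dispersion in edgeR the same calls were lost, at adjusted p of 0.143, 0.176, 0.229 and 0.271. MT-ND3 also lost its call without siNC replicate 1 (adjusted p = 0.0813), without siNC replicate 2 (0.104) and without siSF3B6 replicate 3 (0.114). MT-ATP8 lost it without siNC replicate 2 (0.0767) and without siSF3B6 replicate 3 (0.105), and MT-CO2 without siSF3B6 replicate 3 (0.0533). Without siNC replicate 3 the values were 2.22 for MT-CYB, 2.29 for MT-CO2, 2.37 for MT-ATP8 and 2.59 for MT-ND3.

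Of 40 genes of the mesenchymal state and invasion, 21 rose and 2 fell, also when adjusted over the list alone (median 0.24, adjusted p = 0.000549, and adjusted p = 0.0883 with an estimated correlation). Among its called members of at least 5 CPM, the largest changes were in the collagen crosslinker LOX (1.03), the integrin ITGA2 (0.71), the matricellular protein CCN1 (0.67) and the transcription factor SNAI2 (0.66). Of 23 apoptosis regulators, 11 rose and 3 fell, also when adjusted over the list alone (median 0.12, adjusted p = 0.0132, and adjusted p = 0.153 with an estimated correlation). The pro-apoptotic BMF (1.07) rose, as did the inhibitor of apoptosis BIRC2 (0.67) and CASP2 (0.55), so members of opposing function moved the same way. The apoptosis median was 0.18 to 0.24 without siNC replicate 1, 2 or 3 or siSF3B6 replicate 3, where the filter let in 24 genes. Over the 23 members tested in the full fit it was 0.144, 0.237, 0.136 and 0.215. Without siNC replicate 2 only 6 apoptosis genes rose. With siNC replicate 3 as the lone control the medians of the 2 lists were 0.25 and 0.16.

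**Figure D4:**
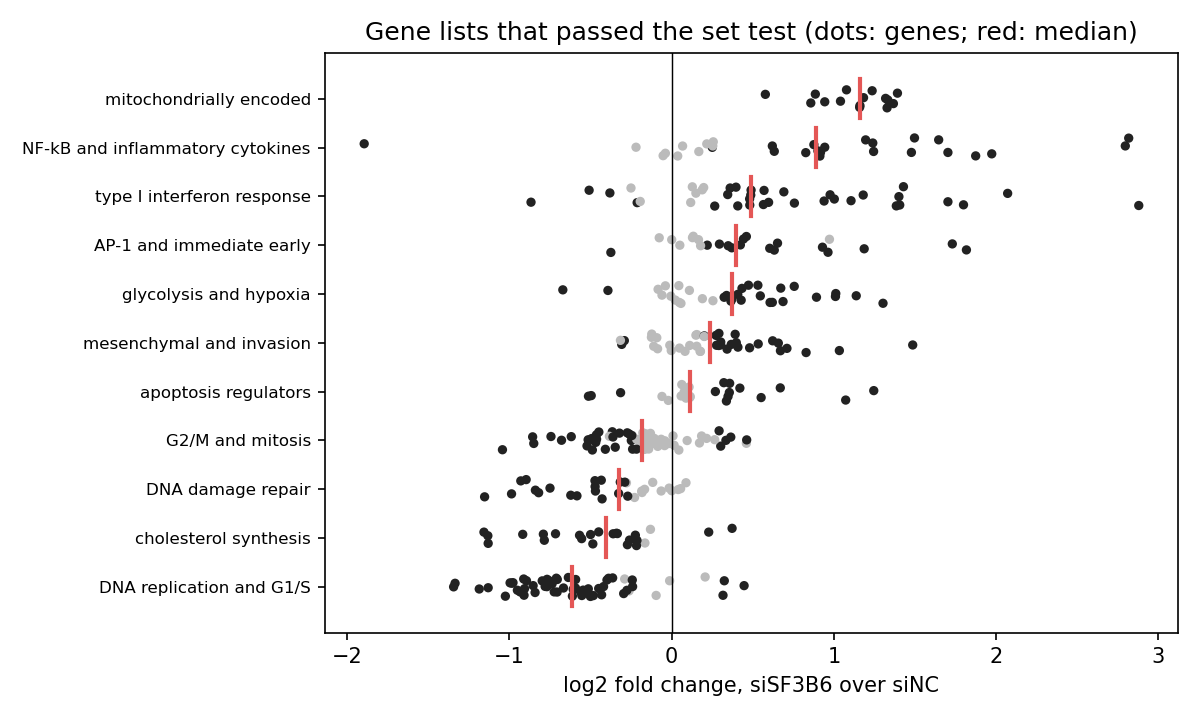
Log2 fold change of siSF3B6 over siNC (x axis) for every tested member of the 11 gene lists that passed the set test; black dots passed the gene threshold, grey dots did not, and red bars mark list medians. Medians run from -0.61 for DNA replication and G1/S to 1.16 for mitochondrially encoded genes.

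None of the lists of splicing factors passed the set test in the fit of all 6 libraries without a replicate block. In the list of SF3a and other U2 snRNP proteins, 2 of 26 genes rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.861), led by SNRPF (-0.47), SNRPB (-0.43), SNRPA1 (-0.29) and SMNDC1 (0.29). SMNDC1 lost its call without siNC replicate 2 (adjusted p = 0.0972), with library size only (0.102) and with the GC and length offset (log2 fold change 0.068, adjusted p = 0.399). For this list the median was 0.037 while the mean and the test pointed down. The median was -0.004 without siSF3B6 replicate 3, and the test pointed up without siNC replicate 3 (adjusted p = 0.991), where 4 rose; without siNC replicate 2, 0 rose. In the list of U1, U4/U6.U5 and catalytic spliceosome proteins, 13 of 42 rose and 10 fell, also when adjusted over the list alone (adjusted p = 0.864), with CWC22 (0.85) and PRPF3 (0.76) higher and EFTUD2 (-0.72) and PRPF31 (-0.70) lower. Its median was -0.015 while its mean and test pointed up, but the median was 0.001 without siNC replicate 1 and 0.013 without siSF3B6 replicate 3, and the test pointed down without siNC replicate 3 (adjusted p = 0.959). Without siNC replicate 2, 8 rose and 6 fell. Of 11 proteins of the minor spliceosome, 4 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.474): SNRNP48 (0.64) and ZCRB1 (0.52) were higher, SNRNP25 (-0.49) and ARMC7 (-0.30) lower; without siNC replicate 1 or 2, 2 rose and 1 fell. ARMC7 lost its call without siNC replicate 1 (adjusted p = 0.0767) or 2 (0.05) and with the GC and length offset (log2 fold change -0.12, adjusted p = 0.137). Among SR proteins and their kinases, 8 of 19 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.134). CLK1 (0.58), SRSF11 (0.50), SRSF8 (0.40) and CLK3 (0.35) changed most among the called members of at least 5 CPM. With the GC and length offset 7 of the 19 rose and 6 fell (median -0.028, adjusted p = 0.847), and without the low-count filter the list passed (adjusted p = 0.00449). Only 4 rose without siNC replicate 2, and the median, 0.155 over all libraries, was 0.083 without siSF3B6 replicate 3. Among hnRNP and tissue splicing regulators, 12 of 35 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.0593), led by HNRNPH3 (0.88), PTBP2 (0.66), RBM39 (0.64) and HNRNPH2 (0.63). This list passed, upward, without siNC replicate 3 (adjusted p = 0.0125), without siSF3B6 replicate 1 (0.0342) or 2 (0.0336) and without the low-count filter (0.000265). It also passed within the libraries numbered 1 and 2, close pairs of narrow spread (19 higher and 9 lower, median 0.13, adjusted p = 0.00822). With the GC and length offset 11 rose and 10 fell, with a median of -0.015 (adjusted p = 0.549). HNRNPH2 shares 16.3% of its exonic bases with a readthrough gene. Of 17 nonsense-mediated decay factors, 3 rose and 4 fell (4 and 5 adjusted over the list alone; adjusted p = 0.823), with SMG6 at -0.55 and UPF2 at 0.44. Their median was 0.026 while the mean and the test pointed down; the median was -0.008 without siNC replicate 2 and -0.069 without siSF3B6 replicate 3. Of 14 snoRNA host transcripts, 3 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.951), with SNHG7 at -0.64 and TAF1D at 0.56. Their median was 0.071 while the mean and the test pointed down, and all 3 pointed up without siNC replicate 3 or siSF3B6 replicate 3 (medians 0.146 and 0.097). The offset moved several of the named splicing and decay genes by over 1.5 times without ending their calls: CLK1 to 0.36, SRSF11 to 0.28, PTBP2 to 0.43, SNRNP48 to 0.42, ZCRB1 to 0.33, SNRNP25 to -0.29, SNRPB to -0.285, SNRPA1 to -0.44, UPF2 to 0.25, TAF1D to 0.33 and SNHG7 to -0.34. UPF2 had 0.27 without siSF3B6 replicate 3. Splice junctions and isoforms were not analysed here.

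The remaining lists did not pass in that fit either. Of 31 CDK inhibitors and p53 target genes, 14 rose and 9 fell (14 and 10 adjusted over the list alone; adjusted p = 0.224), with FDXR (-1.30) and DDB2 (-0.98) changed most; the list passed without the low-count filter (adjusted p = 0.0125). Of 36 genes of the unfolded protein and integrated stress response, 10 rose and 8 fell (12 and 9 adjusted over the list alone; adjusted p = 0.704), among them PHGDH (-0.88) and DDIT4 (0.73); 5 fell without siNC replicate 1, and 15 rose and 6 fell with the offset. In the heat shock list 0 of 14 rose and 4 fell (0 and 1 adjusted over the list alone; adjusted p = 0.278), with HSPD1 at -0.69 and CHORDC1 at -0.26; without siNC replicate 1 or 2 or siSF3B6 replicate 2 only 1 fell. CHORDC1 had -0.505 with the offset, and its call was lost when any library other than siSF3B6 replicate 3 was left out (adjusted p of 0.071 to 0.237). Of 50 nuclear genes of oxidative phosphorylation, 6 rose and 11 fell (6 and 8 adjusted over the list alone; adjusted p = 0.312), with CYC1 at -0.74 (-0.45 with the offset) and NDUFS5 at 0.63. Without siNC replicate 3, 15 rose and 17 fell, and without siNC replicate 1 or 2 only 1 rose. The list passed downward with siNC replicate 3 as the lone control (median -0.12, adjusted p = 0.0461). Of 74 cytosolic ribosomal protein genes, 5 rose and 8 fell (2 and 5 adjusted over the list alone; adjusted p = 0.709), and the list's median and test pointed down while its mean was 0.01. Its direction depended on the libraries: its median and test pointed up without siNC replicate 3 (median 0.025, 23 higher and 15 lower) or siSF3B6 replicate 3 (median 0.044). Within those numbered 1 and 2 it passed upward (41 higher and 19 lower, median 0.13, adjusted p = 7.56e-06), and with siNC replicate 3 as the lone control it passed downward (1 higher and 3 lower, median -0.19, adjusted p = 0.00145). The pass within the libraries numbered 1 and 2 rests on the narrow spread of the close pairs. Only 2 ribosomal genes rose without siNC replicate 1 or 2. RPS10 (1.77) had the largest change but shares 39.4% of its exonic bases with a readthrough gene. RPL39 (0.76) lost its call without siNC replicate 1, without siNC replicate 2 and without siSF3B6 replicate 3 (adjusted p of 0.0698 to 0.0851), and had 1.28 without siNC replicate 3. Its call was also lost with DESeq2 (adjusted p = 0.181) and with robust dispersion in edgeR (0.203). Of 20 histone genes, 6 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.575), with H2AJ at 0.77 and H2BC5 at 0.72; the list's median was -0.039 while its mean and test pointed up. The median had the same sign as the mean without siNC replicate 1 (0.082) or 3 (0.017), without siSF3B6 replicate 1 (0.039, with 3 genes higher) or 3 (0.005) and with the offset (0.079). Of 24 collagen and matrix genes, 7 rose and 4 fell (8 and 5 adjusted over the list alone; adjusted p = 0.593), with FBN1 at 0.80 and COL13A1 at -0.75. Without siNC replicate 3 the test pointed down (adjusted p = 0.889) and the median was 0.034, against 0.104 over all libraries; without siNC replicate 1 or siSF3B6 replicate 1 only 4 rose. Of 16 epithelial junction and keratin genes, 6 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.134), with EPCAM at 1.10 and CLDN1 at 0.77. This list passed upward with the GC and length offset (10 higher and 1 lower, median 0.235, adjusted p = 0.00487), with siNC replicate 3 as the lone control (median 0.22, adjusted p = 0.0473), without siSF3B6 replicate 3 (0.0472) and without the low-count filter (0.00977).

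No list of markers of other cell types passed the set test in the fit of all 6 libraries without a replicate block. Of 13 tested luminal breast epithelial markers, 5 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.13), with ERBB3 at 0.72. Luminal markers passed upward with the GC and length offset (8 higher and 2 lower, median 0.26, adjusted p = 0.0227), with siNC replicate 3 as the lone control (median 0.22, adjusted p = 0.0398) and without the low-count filter (0.0172). Of 7 fibroblast markers, 2 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.454). Of 8 leukocyte markers, 4 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.238). Without the low-count filter the fibroblast and the leukocyte list each had an adjusted p of 0.0468. Without siNC replicate 1, 0 leukocyte markers passed the threshold, and without siSF3B6 replicate 1 or 2, 2 and 1 passed. CD74, at 241 ± 19.2 CPM in siNC, had 0.31 (0.49 with the offset) and lost its call without siNC replicate 1 (adjusted p = 0.0824), without siSF3B6 replicate 1 (0.0657) and without siSF3B6 replicate 2 (0.0518). The lists of endothelial and neuronal markers had 3 and 4 tested members, too few for the set test. Of the former 1 rose and 2 fell, with ESAM at 0.34 and PECAM1 at -0.34, and of the latter 2 rose and 0 fell, in both cases also when adjusted over the list alone. The call of PECAM1 was lost without siNC replicate 1 or 2 and without siSF3B6 replicate 1 or 3 (adjusted p of 0.071 to 0.121), and without siNC replicate 2 or siSF3B6 replicate 1 or 3 no endothelial marker passed downward.

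Because SF3B6 is a spliceosome protein, fold changes were set against gene structure in 13451 protein-coding genes. Introns, length and GC content are those of the longest annotated transcript of each gene, which need not be the one most expressed. That transcript has only 1 intron for SF3B2 and for FDPS, so weak correlations with introns may reflect the choice of transcript. The 469 single-exon genes had a median log2 fold change of 0.062 and the 12982 genes with introns one of 0.001. With the GC and length offset the medians were 0.107 and -0.006. Against the mean of siNC they were 0.077 and 0.009 in siSF3B6 replicate 1 and 0.081 and 0.006 in replicate 2, while replicate 3 went the other way, with -0.019 and -0.007. Across genes, which are not independent replicates, Spearman's rho of the log2 fold change was -0.037 with the number of introns of that transcript. It was 0.133 with transcript length and -0.385 with GC content. The correlation with introns ran from -0.072 without siSF3B6 replicate 3 to -0.013 without siSF3B6 replicate 2 and was -0.08 with the GC and length offset; the siSF3B6 libraries against the mean of siNC had -0.06, -0.085 and 0.022. The correlation with length ran from 0.075 without siSF3B6 replicate 3 to 0.165, and was -0.007 with the offset. The correlation with GC content ran from -0.434 to -0.273 when single libraries were left out. The median went from 0.22 in the decile of lowest GC content to -0.28 in the decile of highest. A trend with GC content also stood between replicates: against the other libraries of its own group, rho was -0.669 for siSF3B6 replicate 3 and -0.481 for siNC replicate 3. With an offset per library for GC content and length, added after the data were examined, 7802 genes were called. Of the 6889 calls, 5841 kept their direction and their place past the threshold. The fit of the 6889 calls has no offset. In simulated counts with the observed GC trends, such a fit made 105 false calls, against 11 with the offset. The simulated trends were the curves that the offset fits, so the lower number with it was favoured in advance. The simulated dispersions came from a fit without the offset and so held GC scatter between replicates. The 105 thus need not carry over to these data. The share of false calls among the 6889 was not estimated.

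**Figure D5:**
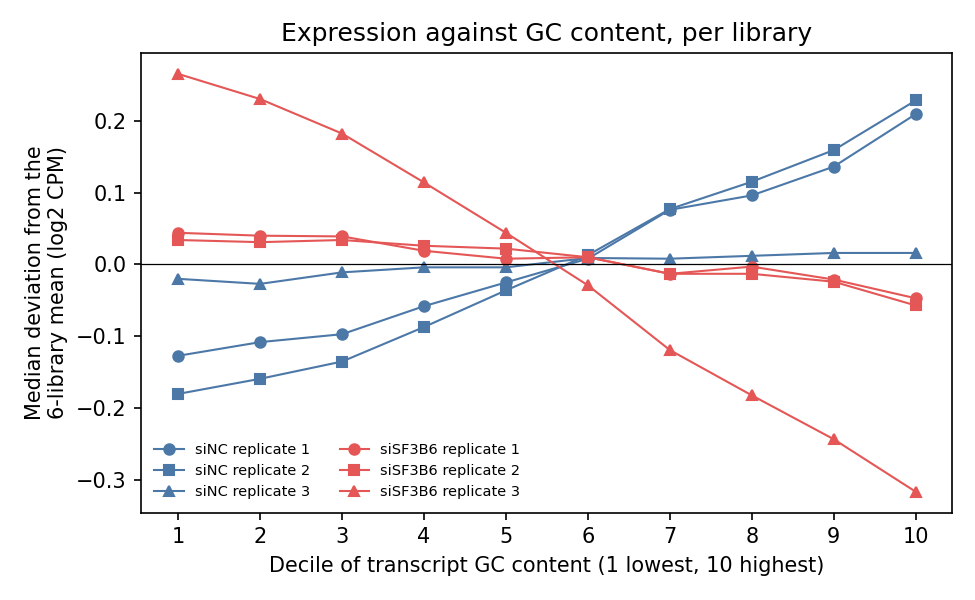
Median deviation of log2 CPM from the mean of the 6 libraries (y axis) in each decile of protein-coding genes by transcript GC content (x axis, 1 lowest to 10 highest), a line per library. siSF3B6 replicate 3 runs from 0.27 to -0.32, and siNC replicate 2 from -0.18 to 0.23.

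An siRNA can lower transcripts whose 3' untranslated region (UTR) matches bases 2 to 8 of its guide strand, the seed. The guide of the SF3B6 duplex gives the match TGAAGCT, found in the longest annotated 3' UTR of 2422 tested protein-coding genes and missing from that of 10947. Genes with the match had a median log2 fold change of -0.025 and those without it one of 0.008. Of 1760 other 7-base words found in a similar number of genes, 204 had a lower shift. Among the 470 of these words with the GC content of the seed match, 0 had a lower shift. Against the mean of siNC, the difference between genes with and without the match was -0.059, -0.051 and 0.022 in siSF3B6 replicates 1, 2 and 3, so that replicate 3 went the other way; the difference of all 6 libraries, -0.033, was -0.057 without that library and -0.022 without siSF3B6 replicate 1. With the GC and length offset the medians were -0.088 and 0.016, and 0 of the 1760 words had a lower shift. The differences of the 3 siSF3B6 libraries were then -0.099, -0.086 and -0.112. Against the other libraries of their own group they lay between -0.011 and 0.011 in each of the 6 libraries, and between -0.044 and 0.081 without the offset. The seed match of the non-targeting guide, TGTCACG, was found in 473 genes, which had a median of 0.048 against 0.001 in genes without it, a higher shift than 594 of 644 words in a similar number of genes. With the offset the medians were 0.035 and -0.004, and 640 of the 644 words had a lower shift. The passenger strand of the SF3B6 duplex gives the match GTTCCTC, found in 1627 genes, which had a median of -0.035 against 0.008; 115 of 2035 words had a lower shift, and 1 of the 486 of the same GC content. With the offset the medians were -0.059 and 0.007, and 2 of the 2035 words had a lower shift. The passenger strand of the non-targeting duplex gives TCGGAGA, found in 399 genes, which had a median of -0.022 against 0.004, and 0.019 against -0.004 with the offset.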

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

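The GC and length offset, the lone siNC control, the libraries numbered 1 and 2 alone, the fit without mitochondrial genes, and the set tests with other filters, RLE factors or robust dispersion were added after the data were examined. SF3B6 stayed lower and past the threshold under all 21 alternatives (log2 fold change -2.16 to -1.81, adjusted p at most 0.0023). The 6889 calls became 2471 with siNC replicate 3 as the lone control, with fewer libraries, and 3817 with unfiltered log2(FPKM + 1). The 680 genes changed at least 2-fold became 1000 without the low-count filter, 435 with at least 1 CPM in 3 libraries and 362 with the lone siNC control. They became 100 with log2(FPKM + 1), 336 with log2(FPKM + 0.1) and 82 without the FPKM filter. A pseudocount shrinks fold changes of low genes; the cause of the other moves was not tested. The 11 lists that passed the set test became 2 with an estimated correlation and 16 with fry, 10 of them among the 11. With fry the mitochondrial list was lost (adjusted p = 0.0828), and SF3b partners (0.0233), heat shock (0.0135), CDK inhibitors and p53 targets (0.0134), epithelial junction genes (0.0233), luminal markers and leukocyte markers (both 0.0191) were gained. Of the other alternatives, all with camera, leaving out mitochondrial genes gave 10, as it removes their list, and the rest gave 11 to 18, each with all 11. Without the low-count filter 18 lists passed, with the lone siNC control 15 and with the offset or the libraries numbered 1 and 2 alone 13. The lists gained with camera were hnRNP and tissue splicing regulators, SR proteins, CDK inhibitors and p53 targets, epithelial junction genes, oxidative phosphorylation, ribosomal proteins, and luminal, fibroblast and leukocyte markers. The ribosomal list, pointing down without passing, reversed and passed upward within the libraries numbered 1 and 2, close pairs of narrow spread (camera adjusted p = 7.56e-06). Of 101 named genes called beside SF3B6, 74 kept their call in every alternative; 24 lost it with the lone siNC control, 20 with unfiltered log2(FPKM + 1) and 8 with DESeq2. SF3B4, not called, reversed to -0.01 with the lone siNC control. With the offset, rho with GC content became -0.017 and rho with length -0.007, as the offset removes these trends, and the seed difference went from -0.033 to -0.104. Pairing by replicate number was not established: deviations of same-numbered libraries correlated at 0.04, 0.106 and 0.136. Each library correlated most with its own number, a hint from the data that leaves shared handling open. With the replicate number as a block, 8052 genes were called and the hnRNP list passed (adjusted p = 0.0288), with no other list changed in its call. Among the named genes the block brought SF3B2 (adjusted p = 0.0254), SF3B3 (0.0281) and PHF5A (0.0238) past the threshold. In the simulation 14% of genes changed 1.25-fold were called at these depths and dispersions with 3 libraries per group; which of these limits it was not tested.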

Other observations

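The tests of seed-matched repression as part of the change, of the passenger strand and of members without a match were chosen after the results were seen, and so were the genes named in this paragraph and the next. Within the list of CDK inhibitors and p53 targets, members went both ways. PMAIP1, a pro-apoptotic BH3 protein (log2 fold change 0.98, SE 0.084), the kinase PLK2 (0.91, SE 0.080) and the CDK inhibitor CDKN1B (0.75, SE 0.081) were higher. CDKN1A (-0.38, SE 0.091), MDM2 (-0.42, SE 0.087) and BAX (-0.51, SE 0.097) were lower, at -0.21, -0.58 and -0.33 with the GC and length offset. All 6 passed the edgeR threshold.

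Inflammatory genes did not move as a block either. The chemokine CXCL2 (1.70, SE 0.122), NFKBIZ (1.24, SE 0.085) and the NF-kB inhibitors TNFAIP3 (1.48, SE 0.118) and NFKBIA (0.94, SE 0.094) rose. The cytokines IL6 (0.07, SE 0.087) and LIF (-0.05, SE 0.085) did not pass the threshold, with adjusted p of 0.563 and 0.659.

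The number of changed genes between siSF3B6 and siNC was 6889, and it was 7802 with the GC and length offset, which argues against GC-dependent library bias as its whole cause. The 6 libraries can be split in 10 ways, too few for a share under 0.05. With edgeR 1 split, the real one, gave 6889 genes and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 8293 genes and the highest of the others 537. Every other split places siNC and siSF3B6 libraries together on each side. The difference between siNC and siSF3B6 then widens the spread within each side, which favours 0 calls there. The other splits thus cannot show how many calls would arise without an siRNA effect, and no conclusion is drawn from them. Seed-matched repression by the SF3B6 siRNA may be a part of the change: with the offset, 0 of 1760 words in a similar number of genes, and 0 of 16142 words found in at least 100 genes, were shifted lower than the guide seed match. The rank-sum z was -12.3 for the guide seed, -6.36 for the next of the words in a similar number of genes, and -6.70 for the seed of the passenger strand, below which 2 of 2035 words lay. Without the offset 204 of the 1760 words, and 0 of the 470 among them with the GC content of the seed match, were shifted lower. There siSF3B6 replicate 3 went the other way (0.022), and the shift did not grow with the length of the match. The difference was -0.031 for an 8-base, -0.033 for the 7-base and -0.029 for a 6-base match. The 8-base and 6-base matches were not compared with the offset. The effect of losing SF3B6 on the remaining genes stays open.

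The lower DNA replication and G1/S genes had a median log2 fold change of -0.61, and of -0.65 with the offset (-0.64 to -0.60 when a single library was left out), which argues against GC-dependent library bias. A seed match lay in an annotated 3' UTR of 13 of the 49 lowered members, 26.5% (exact 95% interval 14.9% to 41.1%), against 21.9% of all 13369 genes searched (Fisher's exact test, two-sided p = 0.488). For those members seed-matched repression cannot be told apart from other causes, since the share was neither past the test nor below that of all genes. The 15 members with a match had a median of -0.78 (-0.69 with the offset) and the 42 without one -0.60 (-0.64 with the offset). The 40 without a match of either strand had -0.59. For members without a match, this argues only against direct repression through the full guide seed match in an annotated 3' UTR. Members with a shorter match, or with one outside the 3' UTR, were not set apart, so repression through those stays open. An effect of SF3B6 loss, or an indirect effect of other lowered genes, stays open and untested.

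The higher interferon and inflammatory genes, 68 in the 2 lists, had a median log2 fold change of 0.61 and of 0.59 with the offset, which argues against GC-dependent library bias. A response to the siRNA duplex itself cannot be told apart from an effect of SF3B6 loss, because the design holds 1 duplex against SF3B6. If a duplex of another sequence lowered SF3B6 without raising these genes, that would speak against an effect of SF3B6 loss. If it raised them, a response common to both duplexes would stay open.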
